A study of Mus musculus with 16 samples.

How the data were processed

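Mesenchymal stromal cells were sorted from the hindlimb muscle of C57BL/6 mice aged 8 weeks, 4 h or 8 h after an intraperitoneal injection of CGRP or PBS. Per the labels, polyadenylated RNA of 1000 double-sorted cells was primed with oligo(dT), amplified by a limited PCR and made into libraries with Nextera XT, which does not mark the strand. The libraries were read on a NextSeq500 as pairs of 25 bases. There are 4 biological replicates in each of the 4 groups, as the submitters describe them, and whether a replicate is 1 mouse or a pool is not given in the sources used here. The marker gate, the dose of CGRP, the collection days and any shared batch are not given either.

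The deposited values are raw read counts per gene, which the authors made, per the processing notes in the labels, by alignment to mm10 with STAR 2.5.4 and counting with featureCounts (version not given). The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The values were checked to be whole numbers, with 1 column per library and 52997 gene symbols. All 16 columns were used. No 2 replicates of a group were the same library: over the 24 pairs within groups, the chi-square of the counts over genes with at least 20 summed reads was 6.52 to 22.7 times its degrees of freedom. Symbols were matched to GENCODE M21 for positions, length and GC content. Of 52997 symbols 49365 matched, and of 13949 tested symbols 13682.

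Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr over the 4 groups, which left 13949, and libraries were scaled with TMM. A quasi-likelihood model with 1 mean per group (12 residual degrees of freedom, robust estimation) was fitted to all 16 libraries. It gave 6 contrasts: CGRP against PBS at 4 h and at 8 h, the mean of these effects, the effect at 8 h minus that at 4 h, and 8 h against 4 h after PBS and after CGRP. The 4 h and 8 h comparisons share no libraries. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold threshold. In the text, rose and fell stand for such calls. The common dispersion corresponded to a biological coefficient of variation of 17.4%. Errors of log2 fold changes are SE and errors of CPM are SD with n = 4. For Il33 and the receptor genes an exact two-sided permutation test of log2 CPM (prior count 0.5) is given beside the model, whose smallest p with 4 against 4 libraries is 0.0286. Where the PBS group held 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. Where it held few counts, the ratio of pooled counts is given with a 95% exact interval. The reads are PCR copies without molecular identifiers, so intervals and floors cover counting error only.

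In all 41 gene lists for this tissue and treatment were written before the data were examined, as were the contrasts, the tests, the naming rule and the alternatives, except where another origin is stated. The 38 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list ranks differently from the other genes. It was repeated with the correlation estimated per list. The directional test of fry asks whether a list's genes move one way on balance, and it does not compare them with other genes. For each list the members called over all genes are counted, and beside them those called when p is adjusted over the list alone. Markers of macrophages, lymphocytes and erythroid cells were summed as CPM.

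Genes are named by a rule. Il33, Calcrl, Ramp1, Ramp2 and Ramp3 are always given. At 4 h and at 8 h, the 10 highest and 10 lowest log2 fold changes are taken among called genes with a mean of at least 5 CPM in the higher group and all 4 CGRP libraries on the same side of the PBS mean. From each list with a camera call or at least 3 called genes up to 4 members with the smallest p are taken, and from any other list described up to 2. For the other contrasts the 8 highest and 8 lowest are taken. Unnamed gene models are left out of the ranking. Genes outside the rule are marked in the text as chosen after their values were seen. The values of 2 genes that the rule names are not reported here.

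The fit was tested on simulated data, in which counts of all 16 libraries were drawn from the pooled profile with each gene's own dispersion and 200 genes were given a known fold. At 4 h, 31.8% of 1.5-fold, 64.1% of 2-fold and 87.3% of 4-fold changes were recovered, and 4.88% of the calls were false. At 8 h the values were 30.8%, 80.6%, 89.4% and 4.32%. In the other contrasts the false share of the calls was 5.19% for the mean effect, 5.75% for the difference, 3.70% for time after PBS and 7.97% for time after CGRP. Genes were drawn independently, so deviations that genes of a real library share are not covered by these rates.

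The alternatives were median-ratio and upper-quartile scaling, no filter beyond 1 read, a strict filter (at least 5 CPM in 4 libraries), DESeq2 1.42.0, voom with sample quality weights, edgeR without robust estimation, counts thinned to the smallest library, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. After the data were seen, fits without the 4 libraries with the most genes detected and without the 3 libraries with the most Gm10800 reads were added. Each count was also compared with other splits of the same libraries: all 35 for 4 against 4, and 100 draws where both times enter. Reads, isoforms and the strand were not analysed here. Positions, lengths, GC content and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.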

Results

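RNA was sequenced from mesenchymal stromal cells (mSC), the connective tissue cells that lie between the fibres of skeletal muscle, sorted from the hindlimb muscle of C57BL/6 mice aged 8 weeks. The mice had received an intraperitoneal injection of CGRP (calcitonin gene-related peptide, a neuropeptide released by sensory nerve endings) or of phosphate-buffered saline (PBS), and the cells were isolated 4 h or 8 h later. There were 4 groups with 4 biological replicates in each, so 16 libraries of 1000 sorted cells. The gene totals ran from 6373713 to 10011920 counts per library: from 7161311 to 10011920 after PBS at 4 h, from 7547621 to 9569539 after CGRP at 4 h, from 6745884 to 7883491 after PBS at 8 h and from 6373713 to 9600027 after CGRP at 8 h. The most abundant transcripts were stromal: gelsolin (Gsn) took 10.6% ± 1.05 of the counts (SD over the 16 libraries), the fibrillar collagen gene Col3a1 1.92% ± 0.492 and the small proteoglycan gene decorin (Dcn) 1.88% ± 0.184. Markers of blood cells were scarce: summed over each list, the group means were 15.4 to 20.5 CPM (counts scaled to the library size) for macrophage and myeloid markers, 1.69 to 3.01 for lymphocyte markers and 118 to 142 for erythroid genes. Some libraries stood apart from the rest. The repeat-derived gene model Gm10800 took 1.77% to 2.45% of the counts in PBS 8 h replicates 1, 2 and 3, and 0.536% to 1.01% in the other libraries. The number of genes with at least 1 read was 25579 in PBS 4 h replicate 4, 25227 in PBS 8 h replicate 4, 24376 in CGRP 4 h replicate 3 and 23294 in PBS 8 h replicate 1, against 21138 to 22341 elsewhere. The sorting gate, the dose of CGRP and the day of each collection are not given in the sources used here.

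At 4 h after injection, the question was which mSC genes CGRP had changed. The neuropeptide gene galanin (Gal) rose from 0.936 ± 1.62 to 87.0 ± 32.8 CPM (mean ± SD, n = 4 in each group), a ratio of pooled counts of 108 (95% counting interval 75.0 to 161, adjusted p = 7.24e-05). PBS 4 h replicate 3 held 26 of the 29 PBS counts of Gal, and without it the ratio was 807 (276 to 3915). Calcb and Calca, whose products include the beta and alpha forms of CGRP, rose from 1 and 2 counts over the 4 PBS libraries. The ratios were 239 (42.5 to 9482, adjusted p = 6.45e-06) and 36.9 (9.83 to 310, adjusted p = 0.00325). Without the 1 PBS library that held those counts, replicate 3 for Calcb and replicate 4 for Calca, the PBS counts were 0. The rises were then at least 61.7-fold and 17.5-fold over a floor of 3 counts. Isoforms were not analysed, so which product the Calca reads encode is not shown. Il33, an alarmin that stromal cells of muscle make, rose from 230 ± 83.8 to 697 ± 214 CPM (log2 fold change 1.60 ± 0.35, adjusted p = 0.00863), and in an exact two-sided permutation test of log2 CPM p was 0.0286, the smallest that 4 against 4 libraries allow. Ugdh, which makes the UDP-glucuronate used for hyaluronan and proteoglycan chains, rose from 520 ± 35.3 to 2605 ± 310 CPM (log2 fold change 2.33 ± 0.10, adjusted p = 3.44e-13). Among the most strongly reduced genes were Adra1a, the alpha-1A adrenergic receptor (-2.06 ± 0.32), P2ry6, a receptor for extracellular UDP (-2.12 ± 0.27), Kcng1, a potassium channel subunit (-2.17 ± 0.35), Blnk (-2.10 ± 0.41), Gabrr2, a GABA receptor subunit (-2.00 ± 0.44), Fam180a (-1.89 ± 0.28) and Stmnd1 (-2.34 ± 0.45). Values in parentheses are log2 fold changes of CGRP over PBS ± SE. The further genes with the largest rises were Ttyh1, a membrane protein (4.39 ± 0.36), Saa2, an acute-phase protein (3.85 ± 0.73), Vdr, the vitamin D receptor (3.67 ± 0.46), Gng4, a G-protein gamma subunit (3.32 ± 0.35), Mrgprg, a receptor of the Mas-related family (3.19 ± 0.58), Hbegf, an epidermal growth factor family ligand (2.74 ± 0.73), and Mt2, a metallothionein (2.57 ± 0.51). The call was lost for Hbegf without any one of CGRP 4 h replicate 4 or PBS 4 h replicates 2 or 3 (log2 fold change 2.01 to 2.54, adjusted p = 0.0545 to 0.0617). In mm10, Gal lies on chromosome 19 at 3409915 to 3414544 (reverse strand), Calca and Calcb on chromosome 7 at 114631478 to 114636357 (reverse) and 114718643 to 114723365 (forward), Il33 on chromosome 19 at 29925114 to 29960718 (forward) and Ugdh on chromosome 5 at 65413221 to 65435949 (reverse).

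Of the genes for the CGRP receptor and its ligands, 8 were tested at 4 h and 4 rose and 1 fell (4 and 2 adjusted over the list alone). The CGRP receptor list had adjusted p = 0.0924 by camera and adjusted p = 0.409 with an estimated correlation. Calcrl, the receptor chain that CGRP and adrenomedullin share, rose from 43.9 ± 8.59 to 71.9 ± 7.59 CPM (log2 fold change 0.71 ± 0.12, adjusted p = 2.55e-04, exact permutation p = 0.0286). Ramp3, a partner chain of Calcrl, rose from 0.156 ± 0.312 to 3.28 ± 0.904 CPM (exact permutation p = 0.0286). Ramp1, which turns Calcrl into the CGRP receptor, stood at 106 ± 26.9 and 95.3 ± 3.04 CPM (log2 fold change -0.16 ± 0.15, adjusted p = 0.551, exact permutation p = 0.543; 0.01 without PBS 4 h replicate 4). Ramp2 stood at 88.0 ± 13.2 and 72.3 ± 9.23 CPM (log2 fold change -0.28 ± 0.12, adjusted p = 0.122, exact permutation p = 0.0571). Among 26 genes of the cAMP and G-protein machinery, 4 fell and 1 rose (4 and 1 adjusted over the list alone). Grk5, a kinase that desensitises receptors (0.96 ± 0.15), rose, and Gnai2, an inhibitory G-protein subunit (-0.39 ± 0.09), Adcy7, an adenylyl cyclase (-0.63 ± 0.14), and the anchoring protein Akap12 (-0.61 ± 0.10) fell. The cAMP machinery list had adjusted p = 0.385 by camera and adjusted p = 0.676 with an estimated correlation. Of 22 target genes of cAMP and CREB, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Among them were Nr4a3, a nuclear receptor induced by cAMP (2.24 ± 0.40), Crem, which encodes a feedback repressor of CREB sites (1.17 ± 0.17), and the phosphodiesterase gene Pde10a (0.76 ± 0.15). The CREB target list had adjusted p = 0.00483 by camera and adjusted p = 0.409 with an estimated correlation. Of 22 immediate early genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone). Among them were Atf3 (0.70 ± 0.16) and Socs3, a feedback inhibitor of cytokine signalling (1.06 ± 0.17). The immediate early list had adjusted p = 0.00523 by camera and adjusted p = 0.546 with an estimated correlation. Of 16 heat shock genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone). The chaperone genes Hsph1 (1.13 ± 0.23), Hsp90aa1 (0.90 ± 0.16) and Hspa8 (0.83 ± 0.13) rose and the small heat shock gene Cryab (-0.58 ± 0.14) fell. The heat shock list had adjusted p = 2.47e-04 by camera and adjusted p = 0.409 with an estimated correlation. Further called members of these lists, chosen after their values were seen, were the adrenomedullin gene Adm (-1.13), Arrb1 (-0.48), Per1 (-1.09), Zfp36 (0.42), Hspe1 (0.69) and Hspd1 (0.93).

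Inflammatory genes of the mSC moved at 4 h in both directions. Of 27 genes of the NF-kB and inflammatory response, 9 rose and 1 fell (11 and 1 adjusted over the list alone). Among them were Tnfaip6, a hyaluronan-binding protein induced by inflammation (1.31 ± 0.27), Sod2, a mitochondrial superoxide dismutase (0.88 ± 0.20), and Stat3 (0.62 ± 0.10). The NF-kB list had adjusted p = 3.52e-04 by camera and adjusted p = 0.409 with an estimated correlation. Among 18 stromal cytokines, 4 rose and 4 fell (5 and 4 adjusted over the list alone). Beside the rise of Il33, Il34, a ligand of the macrophage growth factor receptor (-1.07 ± 0.20), Flt3l (-0.85 ± 0.17) and Tgfb3 (-0.57 ± 0.11) fell. The list median was -0.06 and the mean 0.21, with no shift by camera (adjusted p = 0.899). Of 16 chemokines, 3 rose and 1 fell (4 and 1 adjusted over the list alone). The B-cell attractant Cxcl13 (1.54 ± 0.26) and Cxcl14 (0.91 ± 0.12) rose and the membrane-bound Cxcl16 (-1.17 ± 0.12) fell. With camera the chemokines had adjusted p = 0.30. Of 17 genes of antigen presentation on MHC class I, 8 fell and 0 rose (9 and 0 adjusted over the list alone). Among them were the peptide transporter subunit Tap2 (-0.62 ± 0.08), the immunoproteasome subunits Psmb8 (-0.73 ± 0.11) and Psmb10 (-0.83 ± 0.14) and H2-T22 (-0.62 ± 0.11). The MHC class I list had adjusted p = 4.53e-06 by camera and adjusted p = 0.0686 with an estimated correlation. Of 35 interferon response genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone). Ifit3 (-1.29 ± 0.31) was one of them. The interferon list had adjusted p = 8.03e-05 by camera and adjusted p = 0.453 with an estimated correlation. Of 15 complement genes, 2 fell and 1 rose (2 and 1 adjusted over the list alone). Cd55, which limits complement on the cell surface (0.42 ± 0.11), rose and Clu (-1.17 ± 0.25) fell. The complement list had adjusted p = 0.245 by camera. In the prostaglandin pathway, 2 rose and 2 fell (2 and 2 adjusted over the list alone) of 15. The cyclooxygenase gene Ptgs2 (1.43 ± 0.33) rose and the prostaglandin F receptor gene Ptgfr (-0.78 ± 0.12) fell. The prostaglandin list had adjusted p = 0.164 by camera. Chosen after their values were seen, the cytokine genes Lif (0.98), Clcf1 (0.97) and Csf1 (0.52) were the other rises and Il15 (-0.51) the other fall among the stromal cytokines. The fall among the NF-kB genes, also chosen afterwards, was that of the interleukin 1 receptor Il1r1 (-0.35).

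Matrix and stromal identity genes moved at 4 h in both directions. Of 34 fibrillar matrix genes, 7 fell and 2 rose (11 and 2 adjusted over the list alone). Elastin (Eln, -0.80 ± 0.20), lumican (Lum, -0.78 ± 0.18) and Ogn (-0.48 ± 0.10) fell and versican (Vcan, 0.58 ± 0.15) rose. The fibrillar matrix list had adjusted p = 1.95e-04 by camera and adjusted p = 0.512 with an estimated correlation. Of 18 basement membrane genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone). Smoc2 (-0.59 ± 0.08) was one of them. The basement membrane list had adjusted p = 0.0270 by camera and adjusted p = 0.600 with an estimated correlation. Among 29 matrix remodelling enzymes, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The protease genes Mmp11 (1.03 ± 0.11) and Adamts9, the protease inhibitor Serpine2 (0.46 ± 0.08) and the hyaluronan synthase Has1 (2.56 ± 0.71) rose. The remodelling list had adjusted p = 0.238 by camera. The call was lost for Has1 without any one of CGRP 4 h replicate 4 or PBS 4 h replicates 1, 2 or 4 (log2 fold change 1.93 to 2.51, adjusted p = 0.0711 to 0.0945). Of 24 TGF-beta response genes, 6 fell and 3 rose (6 and 4 adjusted over the list alone). The feedback repressors Tgif1 (0.96 ± 0.17) and Skil (0.72 ± 0.15) rose, and Id3 (-0.58 ± 0.11) and the matrix gene Tgfbi (-0.49 ± 0.10) fell. The TGF-beta list had adjusted p = 0.987 by camera. Of 23 mSC markers, 10 fell and 3 rose (12 and 3 adjusted over the list alone). The falls included the growth factor receptors Pdgfra (-0.40 ± 0.07) and Pdgfrb (-0.65 ± 0.11) and the transcription factors Osr1 (-0.74 ± 0.11) and Tcf4 (-0.52 ± 0.08). The mSC marker list had adjusted p = 1.12e-04 by camera and adjusted p = 0.0686 with an estimated correlation. Markers of the stromal subset with Dpp4 and Pi16 rose in 4 and fell in 0 of 18 (5 and 1 adjusted over the list alone; adjusted p = 0.128 by camera), Ugdh and Cd55 among them. Markers of the subset with Col15a1 and Smoc2 fell in 6 and rose in 2 of 18 (7 and 2 adjusted over the list alone). Vwa1 (-0.93 ± 0.12) and Gdf10 (-1.06 ± 0.16) were lower and Rgcc (2.15 ± 0.23) was higher. The Col15a1 subset list had adjusted p = 7.32e-04 by camera and adjusted p = 0.433 with an estimated correlation. Among 25 myogenic and tissue growth factors, 5 fell and 3 rose (7 and 4 adjusted over the list alone). Fgf10 (1.15 ± 0.21) and Bmp2 (0.64 ± 0.14) rose and Rspo3, an enhancer of Wnt signalling (-1.15 ± 0.27), fell. The growth factor list had adjusted p = 0.899 by camera. Their median, 0.00, turned negative under upper-quartile scaling. Of 23 Wnt pathway genes, 7 fell and 0 rose (8 and 1 adjusted over the list alone), Wnt5a among them (-0.97 ± 0.15). The Wnt list had adjusted p = 0.00247 by camera and adjusted p = 0.212 with an estimated correlation. Of 26 neurotrophin and axon guidance genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone). Among them were Sema5a (-0.88 ± 0.13), neurotrophin 3 (Ntf3, -0.71 ± 0.14), netrin 1 (Ntn1, -0.45 ± 0.10) and Nrp1, a receptor for semaphorins and vascular growth factors (-0.38 ± 0.08). The axon guidance list had adjusted p = 0.0656 by camera and adjusted p = 0.546 with an estimated correlation. Members chosen after their values were seen were Thbs1 (2.10), the other rise among the matrix genes, Timp2 (-0.27), the fall among the remodelling enzymes, Smad7 (0.79), Fgf2 (1.01), Efnb1 (0.88), and the mSC markers that rose, Pdpn (1.15), Twist2 (1.07) and Ly6a (0.26).

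Metabolic genes and markers of other cells also differed at 4 h. Of 23 cholesterol synthesis genes, 13 fell and 1 rose (17 and 1 adjusted over the list alone). The falls included squalene synthase (Fdft1, -1.45 ± 0.25) and the regulator Srebf2 (-0.63 ± 0.12). Phosphomevalonate kinase (Pmvk, 2.13 ± 0.17) was the gene that rose. The cholesterol list had adjusted p = 2.71e-05 by camera and adjusted p = 0.409 with an estimated correlation. Of 26 hypoxia and glycolysis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone). Among them were hexokinase 2 (Hk2, 1.89 ± 0.35), the glucose transporter Slc2a1 (1.60 ± 0.38) and lactate dehydrogenase A (Ldha, 0.69 ± 0.12). The glycolysis list had adjusted p = 0.245 by camera and adjusted p = 0.628 with an estimated correlation. Of 22 genes of the unfolded protein and integrated stress responses, 5 rose and 1 fell (7 and 1 adjusted over the list alone). Among them were Trib3 (1.01 ± 0.26), Xbp1 (0.55 ± 0.13) and Ppp1r15a (0.50 ± 0.13). The stress response list had adjusted p = 0.0306 by camera and adjusted p = 0.610 with an estimated correlation. Of 25 glucocorticoid-responsive genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone). The metallothionein Mt1 (2.11 ± 0.28) and glutamine synthetase (Glul, 0.74 ± 0.16) rose and the receptor itself (Nr3c1, -0.42 ± 0.10) fell. The list median was -0.02 and the mean 0.14. The glucocorticoid list had adjusted p = 0.683 by camera. Of 21 circadian clock genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Bhlhe41 (-0.72 ± 0.18) and Rora (-0.47 ± 0.09) among the falls. The clock gene list had adjusted p = 0.237 by camera. Of 24 vasoactive and angiogenic factors, 6 fell and 3 rose (7 and 5 adjusted over the list alone). The bradykinin receptor Bdkrb1 (2.09 ± 0.41) rose and the angiotensin receptor Agtr1a (-0.75 ± 0.13) and Angptl2 (-0.70 ± 0.12) fell. The vasoactive list had adjusted p = 0.205 by camera. Of 81 ribosomal protein genes, 10 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.16 and Rpl10a (0.36 ± 0.09) and Rpl18 (0.33 ± 0.08) as examples. The ribosomal list had adjusted p = 1.44e-06 by camera and adjusted p = 0.600 with an estimated correlation. Pericyte and smooth muscle markers fell in 5 and rose in 0 of 10 (6 and 0 adjusted over the list alone). Itga8 (-1.67 ± 0.29), Mylk (-1.83 ± 0.41) and Cspg4 (-1.20 ± 0.20) were among them, and the summed level was 124 ± 13.0 CPM after CGRP against 208 ± 26.3 after PBS. The pericyte list had adjusted p = 3.52e-04 by camera and adjusted p = 0.277 with an estimated correlation. Tenocyte markers summed to 691 ± 232 CPM after CGRP and 1271 ± 542 after PBS, and 1 fell and 0 rose (5 and 0 adjusted over the list alone) of 10. The tenocyte list had adjusted p = 0.00244 by camera and adjusted p = 0.497 with an estimated correlation. The gene called was Comp (-1.08 ± 0.34), and the call was lost for Comp without any one of CGRP 4 h replicates 1, 2, 3 or 4 or PBS 4 h replicates 2 or 4 (log2 fold change -1.15 to -0.91, adjusted p = 0.0777 to 0.133). Endothelial markers fell in 2 and rose in 0 of 8 (2 and 0 adjusted over the list alone; adjusted p = 0.637 by camera), Plvap being one (-1.61 ± 0.27). Schwann and perineurial markers fell in 2 and rose in 0 of 12 (3 and 0 adjusted over the list alone; adjusted p = 0.470 by camera), with Pmp22 at -0.35 ± 0.08 (list median -0.04, mean 0.02). None of 9 muscle stem cell markers, 17 myofibre genes or 11 mitochondrially encoded genes passed. By contrast, 1 of 18 adipogenic genes (Scd1, 0.46 ± 0.12) and 1 of 30 cell cycle genes did. Further members chosen after their values were seen were Gapdh (0.26), Asns (0.71), Cdkn1a (0.61), Nfil3 (1.21), Vegfd (0.85) and Bdkrb2 (1.55), which rose, and Herpud1 (-0.30), Cdkn1c (-0.83) and Myh11 (-2.60), which fell.

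Over all 13949 genes tested at 4 h, edgeR called 2262 (16.2%; adjusted p under 0.05), 1094 of them higher and 1168 lower after CGRP (913 and 1381 with upper-quartile scaling), and 4029 had an unadjusted p under 0.05. Of the 38 lists tested, 16 passed camera with its preset correlation (6 up and 10 down), and with an estimated correlation 0 passed; fry called 15. Leaving out CGRP 4 h replicate 4 brought the gene count to 1481. Without the 4 libraries with the most genes detected, a set chosen after seeing the data, Il33 rose by 1.48 on the log2 scale and no longer passed (adjusted p = 0.0758, against 1.09e-04 to 0.0317 for Il33 in the other settings).

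**Figure D1:**
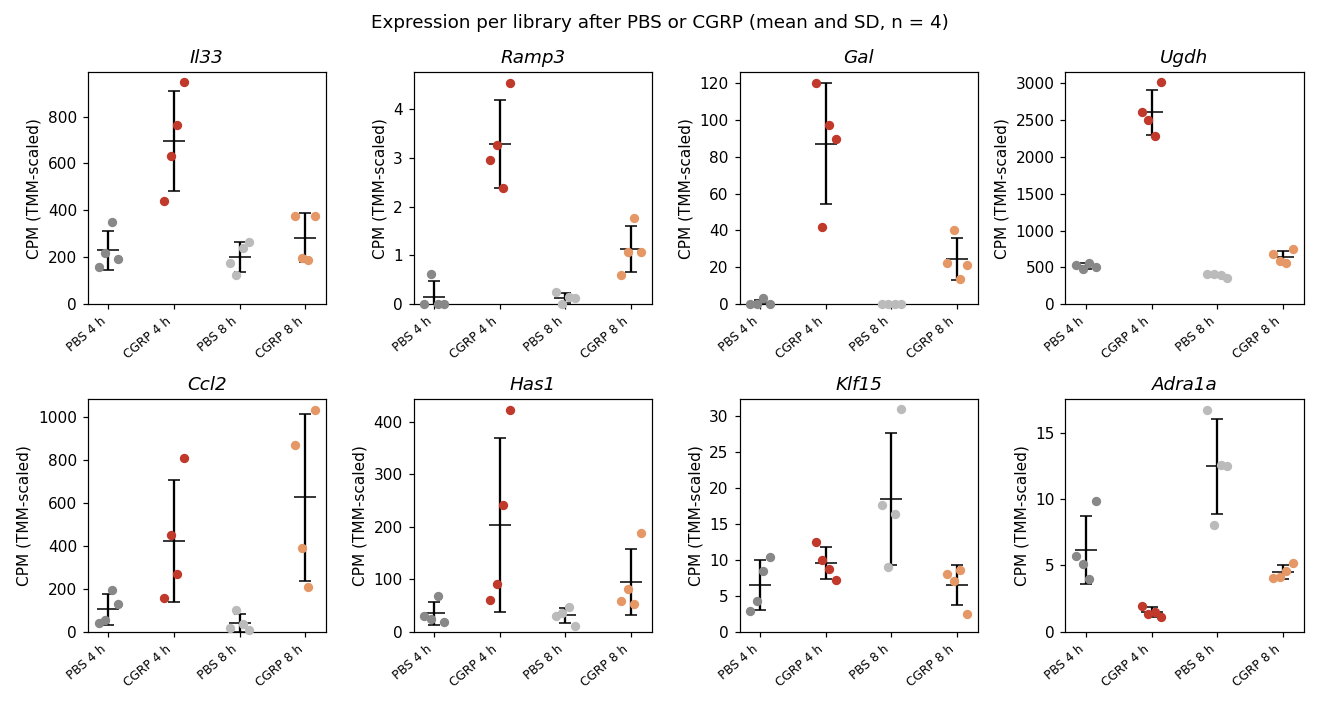
Abundance in CPM of 8 genes in each library (points) with the mean and SD of each group (n = 4), for PBS and CGRP at 4 h and 8 h. At 4 h the Il33 means are 230 ± 83.8 (PBS) and 697 ± 214 (CGRP), and at 8 h 202 ± 63.7 and 284 ± 105; Gal stands at 87.0 ± 32.8 and 24.3 ± 11.3 CPM after CGRP.

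At 8 h after injection, the same question was asked of separate libraries. Gal stood at 24.3 ± 11.3 CPM after CGRP, a ratio of pooled counts of 243 (95% counting interval 83.0 to 1182) over the 3 counts of the 4 PBS libraries, all in replicate 4 (adjusted p = 0.00121). Calca was at least 30.7-fold higher after CGRP than the floor of 3 counts over the PBS group, which had 0 counts (adjusted p = 0.00170). CGRP 8 h replicate 2 held 70 of the 109 Calca counts after CGRP, and without it the bound was 14.9-fold. Calcb had a ratio of 5.39 (2.54 to 13.2, adjusted p = 0.0443) over 8 PBS counts, 7 of them in replicate 3, and without that library the ratio was 33.2 (5.69 to 1335). The call was lost for Calcb without any one of CGRP 8 h replicates 1, 3 or 4 or PBS 8 h replicates 1, 2 or 4 (log2 fold change 1.89 to 2.43, adjusted p = 0.0670 to 0.122) and with edgeR without robust estimation (adjusted p = 0.0512). Among chemokine genes that attract monocytes and neutrophils, Ccl7 (3.58 ± 0.72), Ccl2 from 39.9 ± 42.5 to 624 ± 388 CPM (3.98 ± 0.91) and Cxcl5 (7.15 ± 1.86) rose. Other large rises were those of Fosl1, a subunit of the AP-1 transcription factor (4.13 ± 0.76), Ccdc81 (3.69 ± 0.48), Ttyh1 (3.39 ± 0.40), Timp1, an inhibitor of matrix metalloproteinases (3.08 ± 0.66), and Sphk1, a sphingosine kinase (2.85 ± 0.61). The largest falls were those of Tcap, a titin-binding protein of muscle fibres (-1.56 ± 0.35), Ndnf (-1.53 ± 0.38), the monooxygenase Fmo2 (-1.51 ± 0.29), the glutathione transferase Gsta4, Adra1a (-1.49 ± 0.28), Svopl (-1.48 ± 0.33), the ephrin receptor Epha4 (-1.45 ± 0.24), Cd83 (-1.40 ± 0.31) and the glucocorticoid-induced factor Klf15 (-1.48 ± 0.42). Il33 stood at 202 ± 63.7 after PBS and 284 ± 105 CPM after CGRP (log2 fold change 0.49 ± 0.35, adjusted p = 0.460; exact permutation p = 0.229), not past the threshold. Single libraries ended the calls of Ccl2 without any one of CGRP 8 h replicates 1 or 4 or PBS 8 h replicates 1, 3 or 4 (log2 fold change 3.63 to 3.96, adjusted p = 0.0501 to 0.0591), of Cxcl5 without any one of CGRP 8 h replicates 1 or 4 or PBS 8 h replicates 1, 2, 3 or 4 (log2 fold change 6.66 to 8.39, adjusted p = 0.0655 to 0.0968) and of Klf15 without any one of CGRP 8 h replicates 1, 2 or 4 or PBS 8 h replicates 1, 3 or 4 (log2 fold change -1.59 to -1.11, adjusted p = 0.0652 to 0.115).

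Of the 8 genes for the CGRP receptor and its ligands, 4 rose and 0 fell (5 and 0 adjusted over the list alone) at 8 h. The CGRP receptor list had adjusted p = 0.0253 by camera and adjusted p = 0.473 with an estimated correlation. Calcrl stood at 42.3 ± 2.38 after PBS and 51.7 ± 4.01 CPM after CGRP (log2 fold change 0.29 ± 0.12, adjusted p = 0.144; exact permutation p = 0.0286). Ramp1 stood at 132 ± 15.5 and 110 ± 23.2 (log2 fold change -0.26 ± 0.15, adjusted p = 0.352; exact permutation p = 0.200), and Ramp2 at 100 ± 6.11 and 105 ± 18.7 (log2 fold change 0.07 ± 0.12, adjusted p = 0.784; exact permutation p = 0.686; negative 0.02 without CGRP 8 h replicate 3). Ramp3 stood at 0.135 ± 0.104 and 1.13 ± 0.480 CPM (log2 fold change 2.90 ± 0.84, adjusted p = 0.0335; exact permutation p = 0.0286), a call lost for Ramp3 without any one of CGRP 8 h replicates 2, 3 or 4 or PBS 8 h replicates 1, 2, 3 or 4 (log2 fold change 2.54 to 3.38, adjusted p = 0.0512 to 0.0858). Of 26 genes of the cAMP and G-protein machinery, 2 rose and 0 fell (2 and 0 adjusted over the list alone), the adenylyl cyclase Adcy5 (0.99 ± 0.17) and Grk5 (0.59 ± 0.15; 0.56 and not called without PBS 8 h replicate 3). Of 22 cAMP and CREB targets, 1 fell and 0 rose (1 and 0 adjusted over the list alone). Of 16 chemokines, 5 rose and 0 fell (5 and 3 adjusted over the list alone). Beside those above, Cxcl13 (2.34 ± 0.29) and Cxcl14 (1.28 ± 0.12) rose. The chemokine list had adjusted p = 0.0448 by camera and adjusted p = 0.508 with an estimated correlation. Of 27 genes of the NF-kB and inflammatory response, 3 rose and 0 fell (4 and 0 adjusted over the list alone). The NF-kB list had adjusted p = 0.0286 by camera and adjusted p = 0.508 with an estimated correlation. Of 16 heat shock genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The heat shock list had adjusted p = 0.00321 by camera and adjusted p = 0.504 with an estimated correlation. MHC class I genes fell in 2 and rose in 0 of 17 (2 and 0 adjusted over the list alone), H2-T23 being one (-0.51 ± 0.12). The MHC class I list had adjusted p = 0.0493 by camera and adjusted p = 0.477 with an estimated correlation. Of 35 interferon response genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone). The interferon list had adjusted p = 0.385 by camera. Of 15 complement genes, 2 fell and 0 rose (4 and 2 adjusted over the list alone). The complement list had adjusted p = 0.0594 by camera. Stromal cytokines fell in 1 and rose in 0 of 18 (4 and 3 adjusted over the list alone). Their median was -0.03 and their mean 0.35, and camera gave adjusted p = 0.863.

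Of 29 matrix remodelling genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone) at 8 h. Among them were Timp1, the urokinase receptor Plaur (1.95 ± 0.41), Serpine2 (0.87 ± 0.08) and Mmp11 (0.78 ± 0.11). The remodelling list had adjusted p = 0.00228 by camera and adjusted p = 0.473 with an estimated correlation. Of 34 fibrillar matrix genes, 5 fell and 1 rose (8 and 3 adjusted over the list alone). Ogn (-0.66 ± 0.10) and tenascin X (Tnxb, -0.53 ± 0.09) fell and Vcan (0.86 ± 0.15) rose. The fibrillar matrix list had adjusted p = 0.0444 by camera and adjusted p = 0.743 with an estimated correlation. Of 18 basement membrane genes, 3 fell and 1 rose (7 and 2 adjusted over the list alone), with Smoc2 at -0.42 ± 0.08. The basement membrane list had adjusted p = 0.0444 by camera and adjusted p = 0.671 with an estimated correlation. Of 24 TGF-beta response genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Tgfbi lower (-0.88 ± 0.10). The TGF-beta list had adjusted p = 0.920 by camera. Its median, 0.02, turned negative under upper-quartile scaling. Of 23 mSC markers, 4 fell and 2 rose (9 and 3 adjusted over the list alone). Pdgfra (-0.28 ± 0.07) and Tcf4 (-0.37 ± 0.08) fell, and the surface proteins podoplanin (Pdpn, 1.36 ± 0.21) and Sca-1 (Ly6a, 0.35 ± 0.07) rose. The mSC marker list had adjusted p = 0.0448 by camera and adjusted p = 0.473 with an estimated correlation. Markers of the subset with Col15a1 and Smoc2 fell in 5 and rose in 1 of 18 (6 and 2 adjusted over the list alone). Gdf10 (-0.82 ± 0.16), Vwa1 (-0.60 ± 0.12) and Podn (-0.59 ± 0.09) were among the falls. The Col15a1 subset list had adjusted p = 0.0142 by camera and adjusted p = 0.508 with an estimated correlation. Markers of the subset with Dpp4 and Pi16 rose in 2 and fell in 1 of 18 (3 and 2 adjusted over the list alone), Ugdh rising (0.70 ± 0.10) and Dpp4 itself falling (-0.40 ± 0.09). Their median was -0.13, their mean 0.06 and adjusted p = 0.920 by camera. Of 26 neurotrophin and axon guidance genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone), Sema5a (-1.28 ± 0.14) and Nrp1 (-0.65 ± 0.08) among them. The axon guidance list had adjusted p = 0.0114 by camera and adjusted p = 0.473 with an estimated correlation. Of 23 Wnt pathway genes, 3 fell and 1 rose (3 and 1 adjusted over the list alone), the receptor Fzd4 being lower (-0.69 ± 0.12). The Wnt list had adjusted p = 0.0391 by camera and adjusted p = 0.473 with an estimated correlation. Of 24 vasoactive factors, 3 rose and 2 fell (5 and 4 adjusted over the list alone), Bdkrb1 rising (1.76 ± 0.42). Their median was -0.27, their mean 0.05 and adjusted p = 0.538 by camera. Chosen after their values were seen, Lum (-0.59) and Dcn (-0.26) were the other falls among both the fibrillar and the mSC genes, and Crispld2 (-0.37) fell in the subset with Col15a1 and Smoc2.

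Of 81 ribosomal protein genes, 23 rose and 0 fell (38 and 0 adjusted over the list alone) at 8 h, with a median of 0.22 and Rps6 (0.52 ± 0.10), Rpl18 (0.41 ± 0.08) and Rpl13a (0.56 ± 0.13) as examples. The ribosomal list had adjusted p = 5.81e-12 by camera and adjusted p = 0.504 with an estimated correlation. Of 26 hypoxia and glycolysis genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone). The glycolytic enzymes Pgk1 (0.82 ± 0.13), Gapdh (0.54 ± 0.08), Pkm (0.42 ± 0.08) and Tpi1 (0.36 ± 0.07) were among them. The glycolysis list had adjusted p = 0.00293 by camera and adjusted p = 0.473 with an estimated correlation. Asparagine synthetase (Asns, 1.33 ± 0.24) and its regulator Atf4 (0.44 ± 0.09) rose and Herpud1 (-0.53 ± 0.09) fell among 22 genes of the unfolded protein and integrated stress responses, where 2 rose and 1 fell (2 and 1 adjusted over the list alone). The stress response list had adjusted p = 0.908 by camera. The median, 0.03, turned negative under upper-quartile scaling. Of 23 cholesterol synthesis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was 0.04 and their mean -0.0061. The cholesterol list had adjusted p = 0.920 by camera. Of 25 glucocorticoid-responsive genes, 5 fell and 1 rose (9 and 3 adjusted over the list alone). Klf9 (-0.61 ± 0.13) and Sesn1 (-0.58 ± 0.12) fell and Mt2 (2.55 ± 0.52) rose. The glucocorticoid list had adjusted p = 0.00321 by camera and adjusted p = 0.473 with an estimated correlation. Circadian clock genes fell in 5 and rose in 0 of 21 (9 and 2 adjusted over the list alone). The clock gene list had adjusted p = 0.00228 by camera and adjusted p = 0.473 with an estimated correlation. Myofibre genes, which mark muscle fibres, fell in 3 and rose in 0 of 17 (3 and 0 adjusted over the list alone), with Atp2a1, the calcium pump of fast fibres, at -0.85 ± 0.17. The myofibre list had adjusted p = 0.00160 by camera and adjusted p = 0.473 with an estimated correlation. Their summed level was 305 ± 55.2 CPM in the PBS 8 h group against 194 to 210 in the means of the other 3 groups. Cell cycle genes rose in 2 and fell in 0 of 30 (1 and 0 adjusted over the list alone). The cell cycle list had adjusted p = 0.00228 by camera and adjusted p = 0.504 with an estimated correlation. Their summed level was 228 ± 6.78 CPM in the PBS 8 h group against 320 to 339 in the means of the others. Pericyte and smooth muscle markers had a median of -0.37 and 0 of 10 passed (3 fell and 0 rose adjusted over the list alone). The pericyte list had adjusted p = 0.0453 by camera and adjusted p = 0.504 with an estimated correlation. None of the endothelial, Schwann or tenocyte markers passed, and 1 of 9 muscle stem cell markers rose (Sdc4, 0.86 ± 0.19).

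Over all 13949 genes at 8 h, edgeR called 1210 (8.67%), 698 higher and 512 lower after CGRP, and 3158 had an unadjusted p under 0.05; with upper-quartile scaling the split was 531 higher and 649 lower. By camera 19 of 38 lists passed (8 up and 11 down; 10 without PBS 8 h replicate 2), with an estimated correlation 0 and by fry 2. The gene count fell to 577 without CGRP 8 h replicate 1, 676 without CGRP 8 h replicate 4, and 749, 789 and 696 without PBS 8 h replicates 1, 3 and 4, and, in settings chosen after seeing the data, to 191 without the 4 libraries with the most genes detected and 146 without PBS 8 h replicates 1, 2 and 3. Ttyh1, Cxcl14, Ugdh, Serpine2, Mmp11, Vcan, Ogn, Tgfbi, Sema5a, Nrp1 and Herpud1 kept their 8 h calls in every setting tried.

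**Figure D2:**
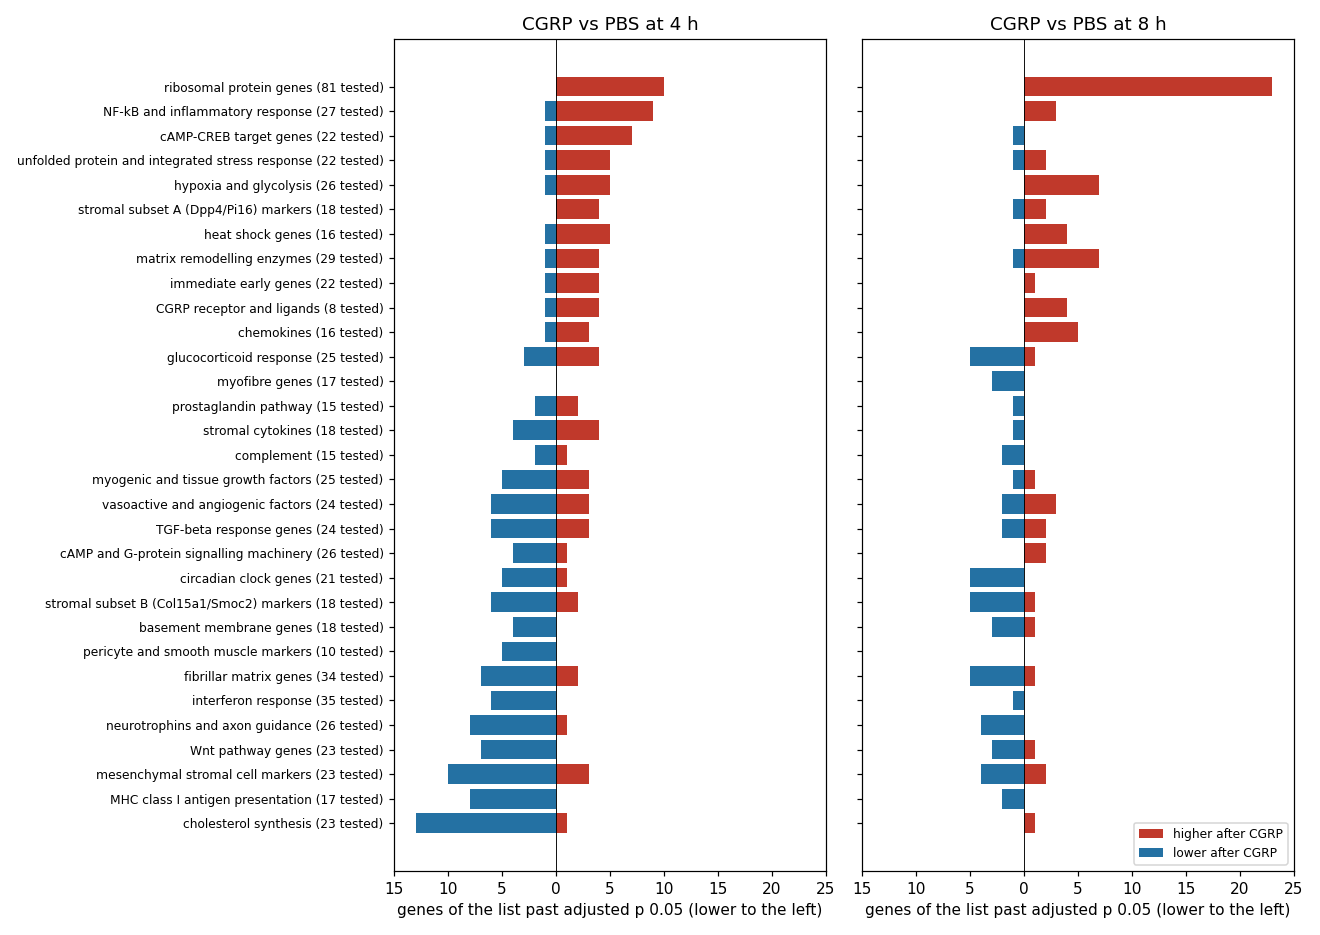
Number of genes called higher (right) and lower (left) after CGRP in each list with at least 3 called genes, at 4 h and at 8 h. Cholesterol synthesis genes stand at 13 lower and 1 higher at 4 h and 0 lower and 1 higher at 8 h; ribosomal protein genes at 10 and 23 higher.

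The mean effect of CGRP over both times also takes in genes called at 1 time alone. Gal, Ttyh1 (3.89 ± 0.26), Vdr (3.43 ± 0.39) and Calcb rose most, with Serpinb2, a protease inhibitor, at 0 and 0.0380 CPM after PBS and 5.13 and 14.8 after CGRP at 4 h and 8 h. The largest falls were those of the apelin receptor Aplnr (-2.06 ± 0.44), Adra1a (-1.77 ± 0.21), Gabrr2 (-1.68 ± 0.31), Stmnd1 (-1.62 ± 0.30), Ndnf (-1.61 ± 0.27) and Kcng1 (-1.58 ± 0.22). Of 81 ribosomal protein genes, 39 rose and 0 fell (48 and 0 adjusted over the list alone), with a median of 0.19. The ribosomal list had adjusted p = 4.74e-12 by camera and adjusted p = 0.453 with an estimated correlation. Of 29 matrix remodelling genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone). The remodelling list had adjusted p = 0.0146 by camera and adjusted p = 0.453 with an estimated correlation. Of 16 chemokines, 7 rose and 3 fell (8 and 3 adjusted over the list alone). The chemokine list had adjusted p = 0.127 by camera. Of 16 heat shock genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone). The heat shock list had adjusted p = 3.11e-04 by camera and adjusted p = 0.453 with an estimated correlation. Fibrillar matrix genes fell in 11 and rose in 2 of 34 (16 and 3 adjusted over the list alone). The fibrillar matrix list had adjusted p = 7.77e-04 by camera and adjusted p = 0.490 with an estimated correlation. The mSC markers fell in 11 and rose in 3 of 23 (13 and 4 adjusted over the list alone). The mSC marker list had adjusted p = 7.77e-04 by camera and adjusted p = 0.144 with an estimated correlation. Pericyte and smooth muscle markers fell in 6 and rose in 0 of 10 (7 and 0 adjusted over the list alone), with a median of -0.89. The pericyte list had adjusted p = 9.64e-04 by camera and adjusted p = 0.356 with an estimated correlation. None of 10 tenocyte markers passed, with a median of -0.68. The tenocyte list had adjusted p = 0.0553 by camera and adjusted p = 0.578 with an estimated correlation. Axon guidance genes fell in 11 and rose in 1 of 26 (11 and 2 adjusted over the list alone). The axon guidance list had adjusted p = 0.0139 by camera and adjusted p = 0.453 with an estimated correlation. In all 3014 genes passed, 1511 higher and 1503 lower (1242 and 1844 with upper-quartile scaling); 1437 did without PBS 8 h replicates 1, 2 and 3. By camera 19 of 38 lists passed, with an estimated correlation 0 and by fry 17.

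The effects at 4 h and 8 h shared genes: 324 were higher at both times, where 54.7 would be expected if the calls were independent, and 233 lower at both (42.9 expected), while 1 was higher at 4 h and lower at 8 h (40.2) and 13 the reverse (58.4). Among them Ttyh1, Ugdh and Cxcl14 were higher and Adra1a, Sema5a and Ogn lower at both. Across the 13949 genes, Pearson's r of the log2 fold changes was 0.42 (0.07 SE from leaving out each of the 16 libraries) and Spearman's rho 0.37. Genes are not independent replicates, and the comparisons share no library. Without the 4 libraries with the most genes r was 0.285, without PBS 8 h replicates 1, 2 and 3 0.185, with no filter on low counts 0.0529 and with the strict filter 0.524. The expression filter was applied anew in each fit, so the first 2 of these values rest on 14605 and 15896 genes. They mix the loss of libraries with added genes of low counts. Of the genes called at 4 h, 82.7% had the same sign at 8 h, and of those called at 8 h, 87.9% had the same sign at 4 h. Because genes vary together, such shares can be high under other groupings. For genes called at 8 h and not at 4 h the share was 79.3%, and other splits of the 4 h libraries gave 23.6% to 78.7%. The highest of these splits kept CGRP 4 h replicates 1, 2 and 4 together.

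**Figure D3:**
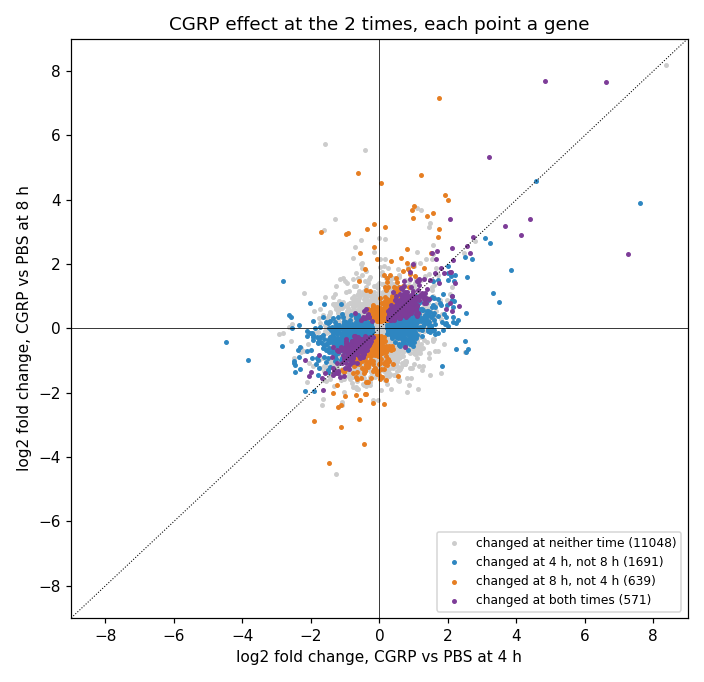
Log2 fold change of CGRP over PBS at 4 h (horizontal) and 8 h (vertical) for each gene tested, coloured by the time at which it passed the threshold. Pearson's r is 0.42 over 13949 genes; 324 genes are higher and 233 lower at both times.

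The test of the difference between the effects (8 h minus 4 h) asked which responses were early or late. Ugdh (-1.62 ± 0.14, adjusted p = 4.28e-07), the nuclear envelope gene Emd (-1.89 ± 0.24), the chemokine scavenger Ackr4 (-1.91 ± 0.36), Rgcc (-1.80 ± 0.34), Pmvk (-1.59 ± 0.24) and Mpp7 (-1.46 ± 0.26) had a more positive effect at 4 h. Plvap, a protein of endothelial fenestrae (2.36 ± 0.37), Fam180a (1.90 ± 0.37), Fdft1 (1.68 ± 0.34) and Rtl3 (1.66 ± 0.23) had a more negative effect at 4 h than at 8 h. Of 23 cholesterol synthesis genes, 3 were more positive and 1 more negative at 8 h (9 and 1 adjusted over the list alone). The cholesterol list had adjusted p = 4.57e-05 by camera and adjusted p = 0.621 with an estimated correlation. Of 22 cAMP and CREB targets, 3 were more negative and 0 more positive at 8 h (5 and 0 adjusted over the list alone). The CREB target list had adjusted p = 2.82e-04 by camera and adjusted p = 0.470 with an estimated correlation. Of 17 MHC class I genes, 2 and 0 were more positive and more negative at 8 h (6 and 0 adjusted over the list alone). The MHC class I list had adjusted p = 0.00129 by camera and adjusted p = 0.470 with an estimated correlation. The difference for Il33 was negative 1.11 and did not pass (adjusted p = 0.324). In all 156 genes passed, 97 more positive and 59 more negative at 8 h; 1996 had an unadjusted p under 0.05. Of the 156, 126 were called at 4 h, 27 at 8 h and not at 4 h, and 3 at neither time. Of the 126, 48 were higher at 4 h with a more negative effect at 8 h, and 77 were lower with a more positive one. The count was 100 and 101 without CGRP 4 h replicates 1 and 4, 100 without CGRP 8 h replicate 3, 85 without PBS 4 h replicate 2, and 80, 89 and 98 without PBS 8 h replicates 1, 3 and 4; it was 456 with no filter on low counts, 427 by DESeq2, 63 without the 4 libraries with the most genes and 53 without PBS 8 h replicates 1, 2 and 3.

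After PBS alone, 72 of 13949 genes differed between 4 h and 8 h. At 8 h Atp2a1 (1.10 ± 0.18) and the adhesion gene Cdh11 (1.17 ± 0.19) were higher and Plac8 (-1.45 ± 0.22) lower. Of 21 clock genes, 1 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.35. The clock gene list had adjusted p = 5.83e-05 by camera and adjusted p = 0.337 with an estimated correlation. Of 35 interferon response genes, 1 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.35. The interferon list had adjusted p = 5.11e-10 by camera and adjusted p = 0.337 with an estimated correlation. Of 30 cell cycle genes, 1 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -1.14. The cell cycle list had adjusted p = 4.03e-08 by camera and adjusted p = 0.337 with an estimated correlation. By camera 17 of 38 lists passed (2 up and 15 down), with an estimated correlation 0 and by fry 0. The fibrillar matrix, remodelling, heat shock, immediate early, NF-kB, MHC class I and stress response lists were among those down, with medians of -0.37 to -0.15. Markers of other cells also differed in their summed level. Myofibre genes stood at 210 ± 40.4 CPM at 4 h and 305 ± 55.2 at 8 h, and pericyte markers at 208 ± 26.3 and 256 ± 26.4. Tenocyte markers stood at 1271 ± 542 and 918 ± 304 CPM. Of the 72 genes 37 were higher and 35 lower at 8 h, and 1817 had an unadjusted p under 0.05. Leaving out PBS 4 h replicates 1, 2, 3 or 4 gave 33, 24, 21 and 280 genes, and PBS 8 h replicates 1, 2, 3 or 4 gave 17, 119, 23 and 30. No filter, DESeq2, a fit of the 2 groups alone and leaving out PBS 8 h replicates 1, 2 and 3 gave 422, 334, 131 and 20. Any batch of collection is confounded with time.

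The libraries at 8 h and at 4 h were also compared after CGRP. Lower at 8 h were Mrgprg (-3.30 ± 0.58), Vdr (-2.61 ± 0.42), Gng4 (-2.59 ± 0.33), Slc6a12 (-2.23 ± 0.22), Calcb (-2.22 ± 0.53), the long pentraxin Ptx3 (-2.17 ± 0.49) and lipocalin 2 (Lcn2, -2.14 ± 0.43). Higher were Kcng1 (2.86 ± 0.34), Aatk (2.60 ± 0.48), Plvap (1.94 ± 0.27), Fam180a (1.87 ± 0.28), the proton channel Hvcn1 (1.86 ± 0.36) and P2ry6 (1.66 ± 0.27). Of 22 cAMP and CREB targets, 8 fell and 0 rose (8 and 0 adjusted over the list alone). The CREB target list had adjusted p = 6.36e-07 by camera and adjusted p = 0.287 with an estimated correlation. Of 22 immediate early genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone). The immediate early list had adjusted p = 2.91e-05 by camera and adjusted p = 0.388 with an estimated correlation. Of 27 NF-kB and inflammatory genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone). The NF-kB list had adjusted p = 9.54e-06 by camera and adjusted p = 0.388 with an estimated correlation. Of 22 stress response genes, 4 fell and 0 rose (10 and 0 adjusted over the list alone). The stress response list had adjusted p = 1.72e-06 by camera and adjusted p = 0.388 with an estimated correlation. The immediate early, NF-kB and stress response lists were also lower at 8 h after PBS alone, with medians of -0.15, -0.24 and -0.37 (adjusted p = 0.00507, 9.10e-04 and 0.00115 by camera, and adjusted p = 0.548, 0.422 and 0.542 with an estimated correlation). Their differences between the CGRP effects did not pass (adjusted p = 0.0761, 0.230 and 0.0829 by camera). Cholesterol synthesis genes rose in 6 and fell in 1 of 23 (11 and 1 adjusted over the list alone). The cholesterol list had adjusted p = 4.78e-05 by camera and adjusted p = 0.388 with an estimated correlation. Pericyte markers rose in 4 and fell in 0 of 10 (6 and 0 adjusted over the list alone). The pericyte list had adjusted p = 1.83e-04 by camera and adjusted p = 0.388 with an estimated correlation. In all 1012 genes passed, 586 higher and 426 lower at 8 h; without CGRP 8 h replicate 2 the count was 666. By camera 10 of 38 lists passed (4 up and 6 down), with an estimated correlation 0 and by fry 8.

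Exons of Ackr4, Adamts9, Atp2a1, Bhlhe41, Cd55, Crem, Cryab, Cxcl16, Dpp4, Eln, Emd, Fdft1, Fgf10, Flt3l, Fosl1, Gapdh, Glul, H2-T22, Hspa8, Hspd1, Hspe1, Hvcn1, Il34, Itga8, Mmp11, Mt2, Mylk, Nrp1, Pdgfra, Pkm, Ppp1r15a, Psmb8, Ptgfr, Ramp2, Ramp3, Rora, Rpl10a, Rpl13a, Rpl18, Rspo3, Serpinb2, Slc2a1, Sphk1, Stat3, Tap2, Tgfb3, Tnxb, Tpi1, Ttyh1, Twist2, Ugdh, Vwa1 and Wnt5a overlap exons of another annotated gene, so some of their reads may belong to the neighbour. Only genes picked by the naming rule were examined for overlap. Others in the text, such as Adm, Per1, Thbs1, Uap1, Gfpt2 and Eprs, were not. Reads of 25 bases also leave the split uncertain between close relatives: Calca and Calcb, Saa1 and Saa2, Mt1 and Mt2, Ccl2 and Ccl7, the H2 genes, and the ribosomal, heat shock and glycolytic genes with processed pseudogenes.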

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

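The share of 8 h calls with the same sign at 4 h, its decision margin and the fits without the 3 PBS 8 h libraries were chosen only after the 8 h result was seen. The ribosomal, neuropeptide and repeat-read tests were chosen after those patterns were seen and before their own results, and the other comparisons of this part before the data were examined.

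Values of 1 library that stood far from the other 3 of its group were found in 7 of 112 groups of values. About 1 in 20, or 5.6, would be picked by chance if the values were normally distributed. That rate does not hold for Calcb, Gal and Ramp3 below, where the other libraries stood at 0 and any read is picked. Calcb stood at 0.129 CPM in PBS 4 h replicate 3 and at 0 in the others. Gal stood at 0.403 CPM in PBS 8 h replicate 4 and at 0 in the others. Klf15 stood at 2.45 CPM in CGRP 8 h replicate 4 (others 7.01 to 8.54). Ramp3 stood at 0.624 CPM in PBS 4 h replicate 2 and at 0 in the others. Stmnd1 stood at 2.32 CPM in PBS 4 h replicate 3 (others 7.80 to 8.12). Ttyh1 stood at 7.19 CPM in CGRP 8 h replicate 3 (others 12.3 to 13.6). The total of CGRP 8 h replicate 4 was 6.37 M counts (others 9.09 to 9.60).

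The effects of CGRP at 4 h and 8 h differed by the test of the difference (8 h minus 4 h, log2) in 156 of 13949 genes. Among 53 named genes 15 differed, a share that the naming rule raises, because it takes, among others, called genes with the largest differences. More positive at 8 h were Ccdc81 (2.74), Plvap (2.36), Fam180a (1.90), Fdft1 (1.68), Rtl3 (1.66), Stard4 (1.52) and Shisa4 (1.28). More negative were Gng4 (-2.20), Ackr4 (-1.91), Emd (-1.89), Rgcc (-1.80), Ugdh (-1.62), Acsl4 (-1.60), Pmvk (-1.59) and Mpp7 (-1.46). Single libraries ended the call for Ccdc81 without any one of CGRP 4 h replicate 1 or CGRP 8 h replicates 2 or 3 or PBS 4 h replicate 3 or PBS 8 h replicates 1, 2 or 3 (log2 fold change 2.36 to 2.73, adjusted p = 0.0508 to 0.0727), Stard4 without any one of CGRP 4 h replicates 2 or 4 or CGRP 8 h replicates 1 or 3 or PBS 4 h replicates 1, 2 or 3 or PBS 8 h replicates 1 or 4 (log2 fold change 1.28 to 1.58, adjusted p = 0.0523 to 0.0747) and Shisa4 without any one of CGRP 4 h replicates 1, 3 or 4 or CGRP 8 h replicates 2, 3 or 4 or PBS 4 h replicates 1, 3 or 4 or PBS 8 h replicates 1, 3 or 4 (log2 fold change 1.10 to 1.31, adjusted p = 0.0525 to 0.0886). The same held for Gng4 without any one of CGRP 4 h replicates 1, 2, 3 or 4 or CGRP 8 h replicates 1, 2, 3 or 4 or PBS 4 h replicate 2 or PBS 8 h replicates 1, 3 or 4 (log2 fold change -2.29 to -1.99, adjusted p = 0.0542 to 0.128) and Acsl4 without any one of PBS 4 h replicate 2 or PBS 8 h replicates 1 or 3 (log2 fold change -1.58 to -1.49, adjusted p = 0.0509 to 0.0565). Of the lists, 10 differed by camera, and none of them with an estimated correlation. Their median differences were 1.66 for tenocyte markers, 1.13 for cell cycle genes, 0.70 for pericyte and smooth muscle markers, 0.61 for cholesterol synthesis, 0.28 for MHC class I genes, 0.16 for interferon response genes and 0.16 for mSC markers. They were -0.47 for cAMP and CREB targets, -0.38 for glucocorticoid-responsive genes and -0.31 for myofibre genes. Cell cycle genes summed to 228 CPM after PBS at 8 h and to 320 to 339 in the other group means. Myofibre genes summed to 305 CPM after PBS at 8 h and to 194 to 210 in the other group means. In both lists the PBS 8 h group alone stood apart.

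Each count was set beside other splits of the same libraries. The smallest share possible is 1 of 35, the real split. The other splits mix the 2 groups compared, so real differences add to their spread and hold down their gene counts. A share of 1 of 35 is thus limited evidence against chance. Only the real split gave as many genes at 4 h (2262, highest other 0) and at 8 h (1210, highest other 0). The same held for genes that differed between times after CGRP (1012, highest other 3) and after PBS (72, highest other 18). Leaving out single libraries moved the 72 genes to between 17 and 280. Only the real split also gave as many lists at 8 h (19, highest other 14). That number of lists was 10 without PBS 8 h replicate 2, 2 by fry and 0 with an estimated correlation. Chance was not excluded for the number of lists at 4 h, because 5 of 35 splits gave at least the real 16 and the highest other gave 18. Of 100 draws that relabelled CGRP and PBS within both times, 1, the real one, gave as many genes in the mean effect (3014, highest other 686). It alone gave as high a correlation (0.42, highest other 0.33). For the gene count the same limit of mixed groups applies. For the difference between times 3 of 100 draws gave as many (156, highest other 1448). The 2 others kept all 4 CGRP labels at 4 h and 1 or 3 of the 4 at 8 h, and gave 1448 and 158 genes. The real grouping at 4 h is thus a structure of the samples that these draws hold. Most other draws also broke that grouping, so they do not test the difference by itself, and chance was not excluded.

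The 81 ribosomal protein genes had a median of 0.19 in the mean effect of CGRP. Against the scaling of libraries as the cause, the median was 0.20 with median-ratio scaling and 0.15, the lower of the pair, with upper-quartile scaling. For short transcripts or GC content, genes matched on length, GC content and expression had a median of 0.00942. The ribosomal genes lay 0.18 above them, and 0 of 10000 matched draws reached the ribosomal median. Length and GC content were those of the longest annotated transcript (median 1094 bases, matched genes 1201), which may not be the one expressed. So this explanation is not settled. The draws took genes independently, while ribosomal genes may move together, so they do not measure chance. Reads shared with processed pseudogenes, whose treatment in the counting is not given, stay open. A wider response of the translation machinery may be a biological explanation, as a hypothesis found and tested on the same data.

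Calca, Calcb and Gal together rose from 0.999 ± 1.61 to 97.3 ± 33.5 CPM at 4 h (SD, n = 4), a ratio of 97.4 (503 without PBS 4 h replicate 3). To look for RNA of sensory neurons carried into the sorted cells, 18 neuron markers were summed, Dbh and Th of sympathetic neurons among them. They stood at 35.9 ± 3.73 CPM after PBS and 30.5 ± 3.18 after CGRP, a ratio of 0.85. The most abundant marker, Tubb3, stood at 18.0 and 11.8 CPM, and 7 of the 18, with Stmn2, Isl1 and Tac1 among them, are expressed enough in these cells to be tested. Tubb3 (log2 fold change -0.66, adjusted p = 0.0159) and Stmn2 (-1.39, adjusted p = 0.0226) fell at 4 h, and Isl1 (0.21) was not called. Tubb3, Isl1 and Stmn2 made up most of the sum after PBS, so the ratio follows these genes and says little of the markers near 0 CPM. Of those, some stood higher after CGRP (Nefm, 0.540 and 1.86 CPM) and some lower (Scn10a, 0.142 and 0.0941 CPM). Against reads of an overlapping gene, 0 bases of the exons of Calca, Calcb and Gal are overlapped by exons of other annotated genes. Transcription of these genes in mSC may be a biological explanation, as a hypothesis. A small amount of RNA from sensory neurons stays open, as does RNA from another cell type without those markers. The marker gate that might remove such RNA is not given.

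At 8 h the comparison rests on PBS libraries of which 3 hold the most Gm10800 reads. The 10 repeat models with the highest rise took 1.7% to 4.6% of the counts of a library. With them left out 1201 genes were called, and 1210 with them, so their share of the counts did not move the calls. TMM scaling allows for such a share in both fits, so little movement was possible, and other differences of those libraries were not tested by it. Whether those libraries account for calls at 8 h could not be decided: of genes called at 8 h and not at 4 h, 79.3% had the same sign at 4 h, where the other splits of the 4 h libraries gave 23.6% to 78.7%. Leaving out 1 PBS 8 h library gave 696 to 1040 genes and leaving out 2 gave 231 to 585. Leaving out all but 1 gave 146 without replicates 1, 2 and 3, and 66, 26 and 53 for the other choices, so the count fell with each of these choices of PBS 8 h libraries, and the set with the most Gm10800 reads kept the highest count of the last 4.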

How the results depend on the processing

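The fits without the 4 libraries with the most genes detected and without PBS 8 h replicates 1, 2 and 3 (the most Gm10800 reads) were chosen after seeing the data; the latter leaves 1 PBS 8 h library, assumed to vary like the other groups. Every other alternative was fixed before. Over the 310 values of single genes, 5470 of 6400 alternatives kept the direction and the side of the threshold, 927 kept the direction and lost the call, and 3 reversed, all of them genes not called: Ramp1 at 4 h (-0.16) was 0.0109 without PBS 4 h replicate 4 and 0.0294 without the 4 libraries (-0.25 to 0.0109 over single left-out libraries), and Ramp2 at 8 h was -0.0215 without CGRP 8 h replicate 3 (-0.0215 to 0.158). Each of the 2 added fits ended 128 of these calls. Il33 at 4 h kept its call except without the 4 libraries (1.48). For values that moved, the cause was not tested beyond the smaller number of libraries. Each fit also applied the expression filter anew. It tested 14605 genes without the 4 libraries and 15896 without PBS 8 h replicates 1, 2 and 3, so genes of low counts were added as libraries were lost. Leaving out in turn each library of the groups compared gave 1481 to 2226 genes at 4 h (2262 with all), 577 to 1279 at 8 h (1210), 80 to 196 for the difference (156), 17 to 280 for time after PBS (72), 666 to 953 for time after CGRP (1012) and 10 to 19 lists at 8 h (19). The lowest were without CGRP 4 h replicate 4, CGRP 8 h replicate 1, PBS 8 h replicate 1 (for the difference and for time after PBS), CGRP 8 h replicate 2 and PBS 8 h replicate 2. Without the 4 libraries the counts were 191 at 8 h and 63 for the difference, and r between the times was 0.285. Without PBS 8 h replicates 1, 2 and 3 they were 146 at 8 h, 1437 for the mean effect, 53 for the difference, 20 for time after PBS and 12 lists at 8 h, with r at 0.185. No filter beyond 1 read gave 456 for the difference, 422 for time after PBS and r = 0.0529, and the strict filter r = 0.524. DESeq2 gave 427 and 334 for the same 2 counts, and only the 2 groups compared 131 for time after PBS. With an estimated correlation 0 lists passed at 4 h and 0 at 8 h, where fry called 2. Under upper-quartile scaling, list medians near 0 turned for TGF-beta response genes and stress responses at 8 h, growth factors at 4 h, adipogenic genes and the subset with Dpp4 and Pi16 in the mean effect and vasoactive factors in the difference. Other planned settings kept the counts within 1.5 times.

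With the replicate number as a replicate block the counts were 2167 at 4 h, 1100 at 8 h, 2960 for the mean effect, 159 for the difference, 69 and 947 for time after PBS and CGRP, and 16 and 18 lists. Not every same-number pair deviated together by over 0.1, so the numbers were not taken to pair the libraries: same-number libraries correlated in their deviations from the group means at -0.05 to 0.08 at 4 h, -0.18 to 0.03 at 8 h, -0.05 to 0.17 between the times after CGRP and 0.07 to 0.12 after PBS (other numbers up to 0.05). Of 24 pairs 4 were over 0.1, and 7 of 16 libraries correlated best with their own number. Between the PBS times every same-number pair lay above all other-number pairs, so a factor shared by number is not excluded there.

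On simulated data 31.8% of 1.5-fold changes were recovered at 4 h and 9.52% for the difference between times, so small changes below the threshold are not shown to be absent.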

Other observations

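The 3 gene lists of this part were written after the main results had been seen, around Gal, Ugdh and Has1 from the results above and around Gfpt2 and Eprs, which were chosen after their values were seen; the thresholds of each test were written before the members of the lists were examined, except that the values of Has2 and Penk, neither of them called, had been seen, and both were taken out of the lists before the tests.

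Genes that charge transfer RNA with amino acids were higher at 4 h. Eprs rose from 165 to 465 CPM, and of the 19 other aminoacyl-tRNA synthetases 15 rose and 0 fell, with a median of 0.43, where 1094 of all 13949 genes rose. Among them were Vars (1.03 ± 0.18), Iars (0.91 ± 0.17), Farsb (0.80 ± 0.13), Wars (0.65 ± 0.11) and Gars (0.62 ± 0.09). Cars, Mars, Qars and Sars were not called. The rise was not confined to 4 h. Some of the 19, such as Kars (0.48) and Yars (0.49), were also called higher at 8 h, and others, such as Iars (0.24) and Vars (0.48), were not. The lists of this part were not refitted with libraries left out. The prediction for a wider rise, at least 0.5 of the list, was met, and it was made on the same libraries as the rise of Eprs, so a shared induction of these genes may be a hypothesis and no more.

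Genes that make UDP-sugars were tested around Ugdh, Has1 and Gfpt2, the last rising from 504 to 1352 CPM (1.42). Of 14 further genes of UDP-sugar and hyaluronan synthesis 4 rose at 4 h: Uap1 from 414 to 1715 CPM (2.05 ± 0.17), Ugp2 (0.72 ± 0.13), Pgm3 (0.60 ± 0.14) and Pgm1 (0.58 ± 0.16). Pgm2 fell (-0.55 ± 0.10). At least 0.5 of the list was needed for a wider rise and under 0.25 against it, so 4 of 14 leaves the hypothesis undecided.

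Other neuropeptide genes were tested around Calca, Calcb and Gal. Of 17 in the list 2 were expressed enough to be tested, and 0 of these rose at 4 h: Tac1 had a log2 fold change of 0.44 ± 0.70 (adjusted p = 0.746) and Nmb one of -0.23 ± 0.29 (adjusted p = 0.675). A wider rise of neuropeptide genes was not seen, on 2 genes.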
